A study of Homo sapiens with 3 samples.

How the data were processed

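The series holds 3 libraries of RAW 264.7 mouse macrophages, 1 each for control, LPS and LB+LPS. The organism field of the labels names human, but the cell line, the source name and the genome build in the submitters' processing notes are mouse, and the samples were treated as mouse. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented and made into dUTP-marked, strand-specific paired-end libraries. The labels name both a HiSeq and a NovaSeq instrument. Nothing in them says that further cultures stood behind a library, and no replicate number is given. The column of the LB+LPS library carries the number 20 after LB, whose meaning is not stated, so no dose is given.

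A table of 22275 genes was used, with Ensembl gene identifiers and symbols paired by the table itself. Per the file headers it holds an FPKM and a count for each gene and library, both deposited by the authors. The deposited FPKM is scaled to transcript length and to the depth of the library. FPKM per count differed between libraries by 1 constant, within 0.05 on the log2 scale, for 100% of the genes over 500 counts. The scaling between libraries therefore did not depend on the gene. A further factor for a whole library would not show in this check. The deposited counts were whole numbers and were not normalized. Whether both mates of a pair were counted is not given in the sources used here. Of all values, 7 had an FPKM of 0 with a count above 0. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the build mm10, with no role or order. Which of them made the table, its annotation release and its handling of strand and of reads with several matches are not given in the sources used here. Reads of near-identical copies and of overlapping genes may therefore be split between them. The coordinates in the table did not look like those of the named build and its header names none, so no coordinates are printed. The reference annotation supplied was human and was not used.

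Total counts of 64539962, 65601581 and 82253323 in control, LPS and LB+LPS put 3 counts, the limit that a count of 0 allows, at 0.0465, 0.0457 and 0.0365 CPM. The 10 most abundant genes took 6.63%, 9.03% and 8.10% of counts. A fold against a library with 0 counts was computed against 3 counts in that library and is given as "at least". This leaves out counting error in the other library, so the exact interval can start lower. Intervals are exact conditional Clopper-Pearson intervals at 95% for the ratio of 2 counts, scaled to FPKM. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, not differences between cultures.

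The design fixed before the data were examined assumed an FPKM table and, with 1 column per group, no test. The table also held counts, but with 1 column per group a count model has no replicates to estimate the spread from, so no DESeq2 or edgeR model was fitted here and the FPKM rule stayed the main result. For each of the 3 comparisons, genes with an FPKM of at least 1 in at least 1 of the 2 libraries were kept, and those with an absolute log2((FPKM + 1)/(FPKM + 1)) of at least 1 were counted. The pseudocount of 1 understates the difference of low genes. Gene lists, 42 in all, were also fixed before the data were examined and cover inflammatory, metabolic, stress and cell cycle genes, RNA quality and markers of other cell types. In each comparison 33 lists had at least 5 measured members. The median of each was set among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, and the percentile describes these libraries.

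The rule for named genes was also fixed beforehand. It takes, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 ratio among genes past the size rule, with a symbol and an FPKM of at least 5 in the higher library, leaving out predicted gene models and pseudogene symbols. It also takes up to 4 members of each list with the largest absolute log2 ratio among those with an FPKM of at least 1, and a panel of 15 inflammatory genes whatever their values. Where a symbol had several rows, the row with the highest mean FPKM was used. The text gives the genes taken by this rule in part, the others entering only the counts of their lists, and 1 of them is not reported here.

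The share of the LPS response kept is the median over genes of the log2 ratio of LB+LPS against control divided by that of LPS against control, with an interval from 1000 bootstrap draws of genes, which are not independent replicates. It was set against 20 simulated sets with no LB effect for each of 3 coefficients of variation between libraries. The size rule was tested on simulated data with counting noise alone, in which 200 genes were changed by 3, 4 or 8-fold. The changed genes were drawn only from those with an FPKM of at least 5 in the library compared against. Recovery of genes below that level, where the pseudocount matters more, was not tested. All 22275 genes entered this step. For LB+LPS against LPS, 100% of the changed genes were recovered at each size, and 3 of 10528 unchanged genes passed. At these sizes and with counting noise alone, recovery follows largely by construction. Changes below 3-fold and differences between cultures were not simulated in this step. Of 200 random lists of 25 among 10981 genes of that comparison, 3.5% lay outside the central 95%. Random lists were set among random lists here, so this share follows largely by construction. It says nothing of lists of genes regulated together. Of the 33 fixed lists, 20 lay outside the range in LPS against control, 19 in LB+LPS against LPS and 19 in LB+LPS against control.

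Alternatives were pseudocounts of 0.1 and 5, size factors, rescaling to TPM, no filter, a filter at an FPKM of 5, sizes of 1.5-fold and 4-fold and, added after seeing the data, genes with a protein-coding transcript alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.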

Results

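RNA sequencing was used to measure gene expression in RAW 264.7 cells, a mouse macrophage line, in 3 groups with 1 library each. Control cells received no drug. LPS cells were stimulated with lipopolysaccharide, a component of the bacterial outer membrane that activates Toll-like receptor signalling, at 0.5 µg/mL for 6 h. LB+LPS cells received LB, components of the root of the plant Lespedeza bicolor, for 30 min before the same LPS stimulation. The labels give no dose of LB. The total gene count was 64539962 in the control library, 65601581 in the LPS library and 82253323 in the LB+LPS library, and 11171, 10609 and 10627 genes, respectively, reached an FPKM of 1. With 1 library per group no difference below has a replicate check, no p-value is given across genes, and "higher" and "lower" describe these libraries. Genes were counted as at least 2-fold different on the log2(FPKM + 1) scale. Folds of single genes are ratios of FPKM, and the bracketed 95% intervals cover counting error only.

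Markers of other cell types were mostly below an FPKM of 1, with the immunoglobulin gene Ighm as the main exception. None of the listed fibroblast, epithelial or endothelial markers reached an FPKM of 1 in either library of any comparison. The T cell list had 1 such gene, Lck, with 0.639, 2.54 and 3.01 FPKM in control, LPS and LB+LPS. The B cell list also had 1, Ighm, with 64.7, 33.9 and 31.8 FPKM, and the neutrophil list had Csf3r, with 3.61, 5.39 and 2.55 FPKM. Of the dendritic cell markers, Itgax had 0.0307, 2.14 and 2.65 FPKM and Ccr7 had 0, 1.16 and 0.265 FPKM. Mitochondrially encoded genes took 5.18%, 4.43% and 4.27% of counts in control, LPS and LB+LPS, and ribosomal RNA genes took 0.181%, 0.260% and 0.101%. The list set as a sign of RNA quality had 5 measured noncoding RNAs, among them Malat1, Neat1 and Gas5. Its median log2 ratio was -0.39 in LPS against control and 0.11 in LB+LPS against LPS. Both lay inside the range of random lists (percentiles 38.3 and 70.6). Its members did not move together between LPS and LB+LPS, with 3 of 5 above 0. Malat1 and Neat1 were lower in LB+LPS, at 38.6 against 46.8 and 8.99 against 10.2 FPKM, and Gas5 was higher, at 61.6 against 38.8 FPKM.

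The first comparison, LPS against control, describes the response to LPS alone. Cytokine, chemokine, interferon-stimulated and NF-kB feedback genes were far higher in the LPS library, while genes of DNA replication, mitosis and mitochondrial respiration were lower. Il1b, which encodes the cytokine interleukin-1 beta, had 961 FPKM with LPS and 0.114 in control, and Tnf (ENSMUSG00000024401), encoding tumour necrosis factor, had 2342 against 34.7 FPKM, 67.6-fold higher (65.5 to 69.8). Csf1r (ENSMUSG00000024621), the receptor for the macrophage growth factor CSF-1, was 16.3-fold lower (15.9 to 16.7), at 21.2 against 345 FPKM. Of 11765 genes with an FPKM of at least 1 in either library, 2857 differed at least 2-fold, 952 of them higher and 1905 lower with LPS, so that 33.3% were higher. Among the 671 genes that differed at least 4-fold, 59.9% were higher. The median log2 ratio of all 11765 genes was -0.34. After rescaling the libraries by median-of-ratios size factors this median was -0.04 and the split was 1317 higher and 1106 lower, or 54.4% higher, so the direction of small differences is best read against the median.

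All 21 measured inflammatory cytokine genes were at least 2-fold higher with LPS, with a list median of 3.59 on the log2 scale. This median lay above those of all 10000 random lists matched on expression. Csf3 (ENSMUSG00000038067), encoding the granulocyte growth factor G-CSF, had the largest log2 ratio by the naming rule, 11.13, with 228947 counts against 4 and 2330 against 0.0414 FPKM. Il1a was at 440 against 0.0887 FPKM and Il27 at 489 against 0.493 FPKM. Il6 had 140 FPKM with LPS and 0 counts in control, and was at least 7740-fold higher when control is set to a floor of 3 counts. On the same floor Il10 was at least 291-fold higher, Il12b at least 55.0-fold and the interferon gene Ifnb1 at least 118-fold. Of 14 chemokine genes, which direct leukocyte migration, 12 were at least 2-fold higher and 1 lower (median 5.86, percentile 100). Ccl3 reached 16610 FPKM against 23.8, Ccl5 reached 1658 against 0.104, Cxcl2 reached 1695 against 0.188, and Cxcl10 reached 259 against 0.565. Ccl22 and Ccl2 had 0 counts in control and were at least 32090-fold and at least 2329-fold higher.

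Of 39 interferon-stimulated genes, 37 were at least 2-fold higher and none lower (median 2.95, percentile 100). Isg15, which encodes a ubiquitin-like protein, had 249 FPKM with LPS and 0 in control. Irf7, a transcription factor of the interferon response, was 154-fold higher (132 to 182), and Usp18 had 57.7 against 0.940 FPKM. Among 24 genes of the NF-kB family and its feedback inhibitors, 22 were at least 2-fold higher (median 3.58, percentile 100). They included Nfkbia, which encodes the inhibitor IkB alpha, 19.3-fold higher (18.7 to 19.9), Nfkbiz, 128-fold higher (118 to 139), Tnfaip3, 69.9-fold higher (64.3 to 76.2), and Zfp36, encoding the mRNA-destabilising protein tristetraprolin, 32.5-fold higher (31.4 to 33.6). Of 21 immediate early and AP-1 genes 14 were at least 2-fold higher and 2 lower (median 2.39, percentile 100). Ier3 stood at 504 against 5.05 FPKM, Atf3 at 172 against 3.86 and Myc at 37.9 against 0.105.

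Enzymes of inflammatory mediators stood in both directions, with 9 of 17 at least 2-fold higher and 4 lower (median 1.55, percentile 100). Nos2, the inducible nitric oxide synthase, had 123 FPKM with LPS and 0.0119 in control, where it had 4 counts, a ratio of 10295 (4020 to 37785). Ptgs2, encoding cyclooxygenase-2, had 2806 against 0.682 FPKM, and Acod1, the enzyme that makes itaconate, had 3210 against 0.870 FPKM. Ptgs1, encoding the constitutive cyclooxygenase-1, was 34.9-fold lower (31.4 to 39.0). Alox5ap, which is needed for leukotriene synthesis, was 18.0-fold lower (16.0 to 20.2).

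Genes for DNA replication and S phase were lower in 33 of 33 cases, 27 of them at least 2-fold (median -1.69, below all 10000 random lists). Thymidine kinase, Tk1, was 17.8-fold lower (16.6 to 19.0), and the cyclins Ccne1 and Ccne2 had 2.40 against 19.1 FPKM and 2.61 against 19.0 FPKM. All 32 mitotic and G2/M genes were also lower, 16 of them at least 2-fold (below all 10000 random lists), with Ccna2 at 20.6 against 82.0 FPKM and Mki67 at 31.7 against 100 FPKM. The 32 nuclear-encoded genes of oxidative phosphorylation were all lower, 9 of them at least 2-fold (median -0.76, percentile 0.01), including the succinate dehydrogenase subunits Sdha, Sdhb and Sdhd with log2 ratios of -1.32, -1.27 and -1.37. With size factors the medians of these 3 lists were -1.36, -0.66 and -0.41. Glycolysis genes had a median of 0.30 (percentile 99.59), 5 of 20 at least 2-fold higher, and the glucose transporter gene Slc2a1 was 7.60-fold higher (7.41 to 7.80).

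Stress genes were higher as well. Of 26 genes of the integrated stress and unfolded protein responses, 14 were at least 2-fold higher and none lower (median 1.15, percentile 100). They included Trib3, 37.3-fold higher (30.1 to 46.7), and Chac1, 22.4-fold higher (18.9 to 26.8). Targets of NRF2, the transcription factor of the antioxidant response, had no common direction relative to other genes, with 3 of 25 at least 2-fold higher and 8 lower (median -0.39, percentile 14.46). Within this list Slc7a11, the cystine transporter subunit, and Hmox1, heme oxygenase-1, were 11.6-fold (10.9 to 12.4) and 3.22-fold higher (3.06 to 3.38), whereas catalase, Cat, had 6.34 against 30.0 FPKM. Mt2, a metallothionein gene, was 32.6-fold higher (29.4 to 36.3). In its list, named metallothioneins and zinc export, 3 of 5 genes were at least 2-fold higher (median 1.30). They were Mt1, Mt2 and the zinc importer gene Slc39a14, while the zinc exporter gene Slc30a1 was 1.85-fold lower (1.69 to 2.02). Of 22 apoptosis regulators 9 were at least 2-fold higher and 3 lower (median 0.66), led by Bcl2a1a, Bcl2a1d and Bcl2a1b, near-identical copies whose separate values are uncertain. The p53 target list had 7 of 16 at least 2-fold higher and 3 lower (median -0.01, percentile 95.08), with Plk2 128-fold higher (92.4 to 181) and Sesn1 13.7-fold lower (12.8 to 14.7).

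Genes of macrophage identity were split, with 5 of 20 at least 2-fold higher and 7 lower (median -0.56, percentile 0.89). Besides Csf1r, the lysozyme gene Lyz2 had 344 against 1675 FPKM and Laptm5 had 27.6 against 235 FPKM, while the inhibitory Fc receptor gene Fcgr2b was 55.1-fold higher (47.0 to 65.2). Genes of MHC class II and costimulation had 6 of 8 at least 2-fold higher (median 2.42, percentile 100), among them Cd40, 214-fold (173 to 267), and Cd80, 36.9-fold (28.4 to 48.9). MHC class I genes had 5 of 19 at least 2-fold higher (median 0.65, percentile 100), with the peptide transporter gene Tap1 5.13-fold higher (4.85 to 5.43). Matrix proteases and inhibitors had 6 of 9 at least 2-fold higher and 1 lower (median 1.65). Toll-like receptors and adaptors were mixed, 7 of 27 higher and 5 lower by at least 2-fold (median -0.03, and 0.25 with size factors). Osteoclast genes had 3 of 6 at least 2-fold higher and 2 lower (median 0.69), iron and heme genes 5 of 14 higher and 2 lower (median 0.48), and alternative activation markers 2 of 7 each way (median 0.26). Heat shock genes had a median of 0.18, with 1 of 15 at least 2-fold higher. Of the aryl hydrocarbon receptor targets only Tiparp was measured, with a log2 ratio of 2.25. The histone list had 3 measured genes, of which 2, H1f2 and H1f0, were at least 2-fold lower. Several medians below 0 were above 0 with size factors. They included ribosomal proteins (-0.22 and 0.13), cholesterol biosynthesis (-0.29 and 0.05), lysosome (-0.28 and 0.03), autophagy (-0.20 and 0.12), housekeeping genes (-0.27 and 0.07) and p53 targets (-0.01 and 0.33). Mitochondrially encoded genes also crossed 0, by little, with a median of -0.35, and 0.004 with size factors. Cholesterol efflux and LXR targets had a median of -0.32, with 4 of 13 at least 2-fold lower and 1 higher, Abca1 (5.54 against 0.961 FPKM). The inflammasome sensor gene Nlrp3 was 10.2-fold higher (9.86 to 10.5), while the median of its list of 15 genes was -0.11, and 0.23 with size factors. The 10 lowest genes by the naming rule, besides those given above, were Ranbp3l (0.0174 against 69.6 FPKM), Trem2, a lipid-sensing receptor gene (1.01 against 48.8), Kbtbd11 (1.54 against 46.3), Susd3 (0.523 against 17.6), Bmyc (2.11 against 36.8) and Shtn1 (1.13 against 23.7). Arg1, an enzyme gene of alternative activation, was near the floor with 29 counts against 9.

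**Figure D1:**
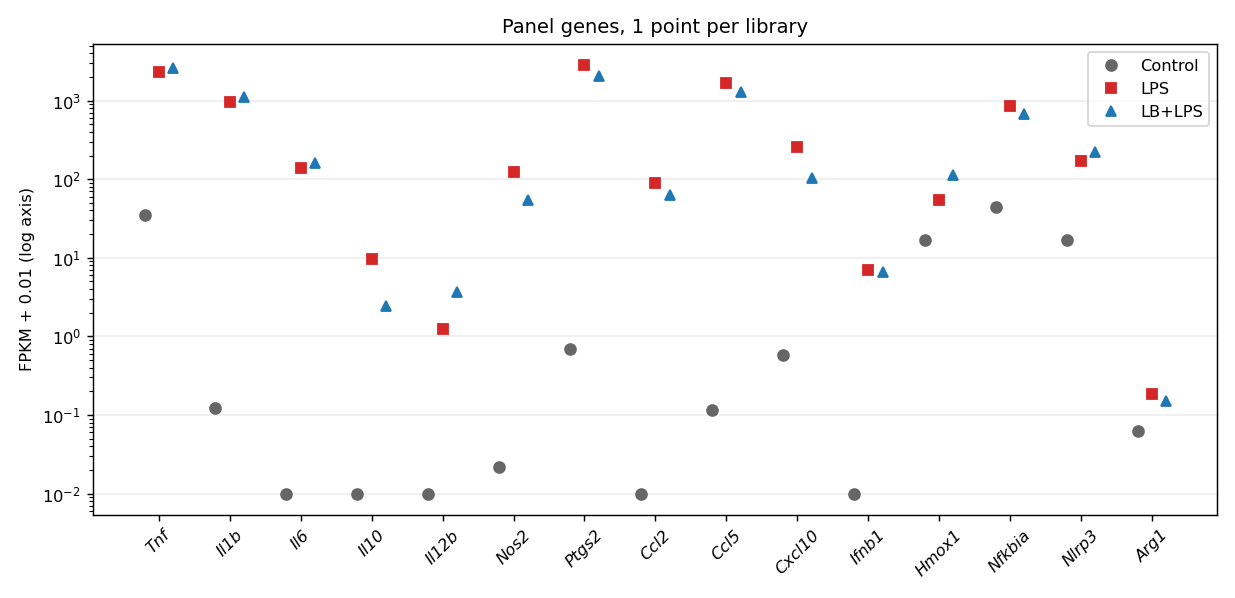
FPKM plus 0.01, on a log axis, of the 15 panel genes in the control (circles), LPS (squares) and LB+LPS (triangles) libraries, 1 point per library and no error bars. Tnf lies at 34.7, 2342 and 2600 FPKM, Nos2 at 0.0119, 123 and 54.3, and Hmox1 at 16.9, 54.3 and 115.

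The second comparison, LB+LPS against LPS, describes how LPS-stimulated cells differed with and without the Lespedeza components. No library received LB without LPS. A change in the LPS response therefore cannot be told apart from an effect that LB has on its own. Most of the transcriptome was close in both libraries. Among the gene lists, NRF2 targets and integrated stress response genes were higher with LB, and chemokines, several interferon-stimulated and feedback genes, glycolysis genes and cholesterol efflux genes were lower. Cxcl10 (ENSMUSG00000034855), a chemokine gene, was 2.53-fold lower (2.48 to 2.57) at 103 against 259 FPKM, and Nos2 (ENSMUSG00000020826) was 2.26-fold lower (2.22 to 2.30) at 54.3 against 123 FPKM. Tnf, Il6 and Il1b were not lower, at 1.11-fold (1.10 to 1.12), 1.13-fold and 1.14-fold of the LPS library. Gclm, a subunit of the enzyme that limits glutathione synthesis, was 2.96-fold higher (2.85 to 3.07) at 23.8 against 8.04 FPKM.

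Of 10981 genes measured, 201 differed at least 2-fold, 63 higher and 138 lower, so that 31.3% were higher. With size factors 57 were higher and 177 lower (24.4% higher). After rescaling to TPM, which also makes the pseudocount act as a smaller one, 43.5% of 695 genes were higher, and with a pseudocount of 0.1 alone 36.4% of 484. With genes that have a protein-coding transcript alone, a restriction chosen after the data were seen, the count was 129, with 29 higher and 100 lower. The median log2 ratio of all genes was 0.06, and 10210 genes (93.0%) lay within 1.5-fold. For the 6924 genes with an FPKM of at least 5 in either library, the central 90% of log2 ratios ran from -0.50 to 0.47. In simulated libraries in which LB did nothing, the same range was -0.32 to 0.32 with a coefficient of variation of 10% between libraries, -0.63 to 0.62 with 20% and -0.93 to 0.93 with 30%, so that the observed range lay between those of 10% and 20%.

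The chemokine list was lower in 13 of 14 genes, 4 of them at least 2-fold (median -0.36, below all 10000 random lists). Cxcl11 was 9.98-fold lower (9.16 to 10.9), Cxcl3 14.3-fold (11.5 to 18.1) and Ccl7 3.81-fold (3.08 to 4.74), while Ccl2 was 1.43-fold (1.38 to 1.48) and Ccl5 1.28-fold lower (1.27 to 1.29). Cxcl11, Cxcl3 and Ccl7 were of low abundance, at 17.7, 4.05 and 6.29 FPKM with LPS. The far more abundant Ccl3 stood at 13757.5 against 16610.4 FPKM. Cxcl2, the 1 gene above 0, stood at 2207 against 1695 FPKM. Inflammatory cytokines were mixed, with 12 of 21 below 0, 5 at least 2-fold lower and 1 at least 2-fold higher (median -0.17, percentile 0.32). The lower ones included 2 genes with anti-inflammatory products, Il10, 3.98-fold lower (3.48 to 4.57), and Il1rn, the interleukin-1 receptor antagonist, 2.64-fold lower (2.61 to 2.67). Il15 was 4.07-fold lower (3.46 to 4.81) and Il33 2.61-fold lower (2.37 to 2.88). Il12b was higher, at 3.69 against 1.22 FPKM, and Ifnb1 stood at 6.59 against 6.92 FPKM, with an interval of 0.910 to 1.21 for the fold by which it was lower.

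Interferon-stimulated genes lay below 0 in 31 of 39 cases, 3 of them at least 2-fold lower (median -0.21, percentile 0). Ifit2 was 4.75-fold lower (4.47 to 5.05), Rsad2, encoding the antiviral enzyme viperin, 3.54-fold (3.32 to 3.78) and Mx1 6.70-fold (5.22 to 8.70). Mx1 was low in both libraries, at 0.250 against 1.68 FPKM. More abundant members moved less, with Isg15 at 215 against 249 FPKM and Usp18 at 58.9 against 57.7 FPKM. The NF-kB family and feedback list lay below 0 in 18 of 24 cases (median -0.26, percentile 0), and 3 genes were at least 2-fold lower. These were the phosphatase gene Dusp1, 3.26-fold (3.15 to 3.38), Bcl3, 2.82-fold (2.71 to 2.93), and Zfp36, 2.17-fold (2.15 to 2.19), and Nfkbia was 1.24-fold lower (1.23 to 1.25). Immediate early and AP-1 genes had 15 of 20 below 0 (median -0.25, percentile 0), with the nuclear receptor gene Nr4a1 6.17-fold lower (5.78 to 6.59) and Fosl2 2.71-fold lower (2.63 to 2.80). Of 16 mediator enzymes 2 were at least 2-fold lower, Nos2 and Ass1, the latter 3.23-fold (2.92 to 3.58), and none was at least 2-fold higher (median -0.10, percentile 2.39). Ptgs2 was 1.37-fold lower (1.36 to 1.37).

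NRF2 targets were above 0 in 22 of 25 cases, 5 of them at least 2-fold higher and none lower (median 0.57, above all 10000 random lists). Srxn1, encoding sulfiredoxin, was at 29.4 against 12.3 FPKM, Slc7a11 at 29.2 against 13.0 FPKM, Hmox1 at 115 against 54.3 FPKM, and Sqstm1, encoding the autophagy receptor p62, at 557 against 277 FPKM. Genes of the integrated stress and unfolded protein responses were above 0 in 25 of 26 cases (median 0.50, percentile 100). Trib3 was at 58.4 against 21.9 FPKM, the only gene of that list at least 2-fold higher, and Ddit3, encoding the transcription factor CHOP, at 35.5 against 17.6 FPKM with a log2 ratio of 0.97. Atf5 and Creld2 had log2 ratios of 0.87 and 0.77. The top genes by the naming rule also held Slc1a4, a neutral amino acid transporter gene, at 21.7 against 9.14 FPKM, the stress gene Gadd45a at 7.23 against 1.66 FPKM, and Aqp9 at 5.45 against 1.28 FPKM.

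Glycolysis genes were lower in 20 of 20 cases, 2 of them at least 2-fold (median -0.32, below all 10000 random lists). Pfkfb3, whose product raises the activator of phosphofructokinase, was 3.23-fold lower (3.15 to 3.30) and hexokinase-1, Hk1, stood at 21.7 against 46.5 FPKM. The pyruvate dehydrogenase kinase gene Pdk1 had a log2 ratio of -0.88. Eno2, an enolase gene named by its size alone, was 5.03-fold lower (4.80 to 5.28). The mitophagy receptor gene Bnip3 was 2.40-fold lower (2.32 to 2.48), although the autophagy list of 16 genes as a whole was slightly higher (median 0.21, percentile 98.93). Oxidative phosphorylation genes had a median of 0.11 (percentile 91.41), and none of the 32 differed at least 2-fold.

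Cholesterol efflux and LXR target genes lay below 0 in 10 of 13 cases, 4 of them at least 2-fold lower (median -0.42, percentile 0). The sterol exporter gene Abca1 was 16.3-fold lower (14.5 to 18.3), the desaturase gene Scd2 5.57-fold (5.40 to 5.75) and Mylip 3.39-fold (3.08 to 3.73), and Scd1 stood at 1.43 against 3.93 FPKM. Scd1 and Scd2 are related genes whose reads may be shared. Cholesterol biosynthesis genes had a median of -0.06 (percentile 1.43) and none of 22 differed at least 2-fold. Plau, encoding urokinase, was 3.92-fold lower (3.33 to 4.62), in a list of 8 matrix genes with a median of -0.23 (percentile 0.98). The iron hormone gene Hamp had 0 counts with LB against 36 and was at least 15.1-fold lower.

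Genes of S phase and of mitosis and G2/M, which were low with LPS, had medians of -0.08 (percentile 0.15) and -0.02 (percentile 3.53), the latter 0.01 after rescaling to TPM, with no gene of either list differing at least 2-fold. MHC class I genes (median -0.16, percentile 0.15), macrophage identity genes (median -0.20, percentile 0.01) and lysosome genes (median -0.14, percentile 0.20) were slightly lower. Toll-like receptor and inflammasome lists had medians of 0.07 and 0.12, and Nlrp3 was at 223 against 172 FPKM. Medians of ribosomal proteins, heat shock genes, apoptosis regulators and housekeeping genes were 0.06, 0.05, 0.03 and 0.04, and with size factors -0.02, -0.03, -0.04 and -0.04. Mitochondrially encoded genes had a median of -0.02, or 0.01 with TPM. The list named metallothioneins and zinc export (median -0.42, percentile 0.26) and alternative activation markers (median -0.35, percentile 0.875) were lower. The former also holds zinc importer genes, and 4 of its 5 genes lay below 0. Mt1 was 1.73-fold and Mt2 1.34-fold lower. The only gene at least 2-fold lower was the zinc importer gene Slc39a10, 2.41-fold (2.29 to 2.53). The zinc exporter gene Slc30a1 went the other way, 2.22-fold higher (2.05 to 2.41), so the list median does not describe zinc export. Medians were -0.16 for osteoclast genes, 0.11 for p53 targets, 0.13 for iron and heme genes and 0.19 for MHC class II and costimulation, each within the central 95% of random lists. In the last list the middle value was that of the costimulation gene Cd40, at 88.6 against 77.4 FPKM, and it does not describe class II genes alone. Tiparp had a log2 ratio of -1.17. The remaining genes among the 10 lowest by the naming rule were Apold1 (0.0513 against 5.15 FPKM), Atp2a3 (1.95 against 14.4), Sdc3 (1.59 against 10.9), the ribosomal RNA gene Rn18s-rs5 (182 against 911) and Guca1a (0 counts against 368). Among the highest were also Itprip (5.28 against 0.178 FPKM), Glrp1 (8.96 against 3.39) and Rpl7a (158 against 69.6). Guca1a, Itprip and Rpl7a overlap other listed genes on the same strand, so that reads of these genes may be assigned elsewhere. Same-strand overlaps were also listed for Gclm, Slc7a11, Pfkfb3, Nr4a1, Dusp1 and Mylip, among others. Their effect on the values was not tested.

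**Figure D2:**
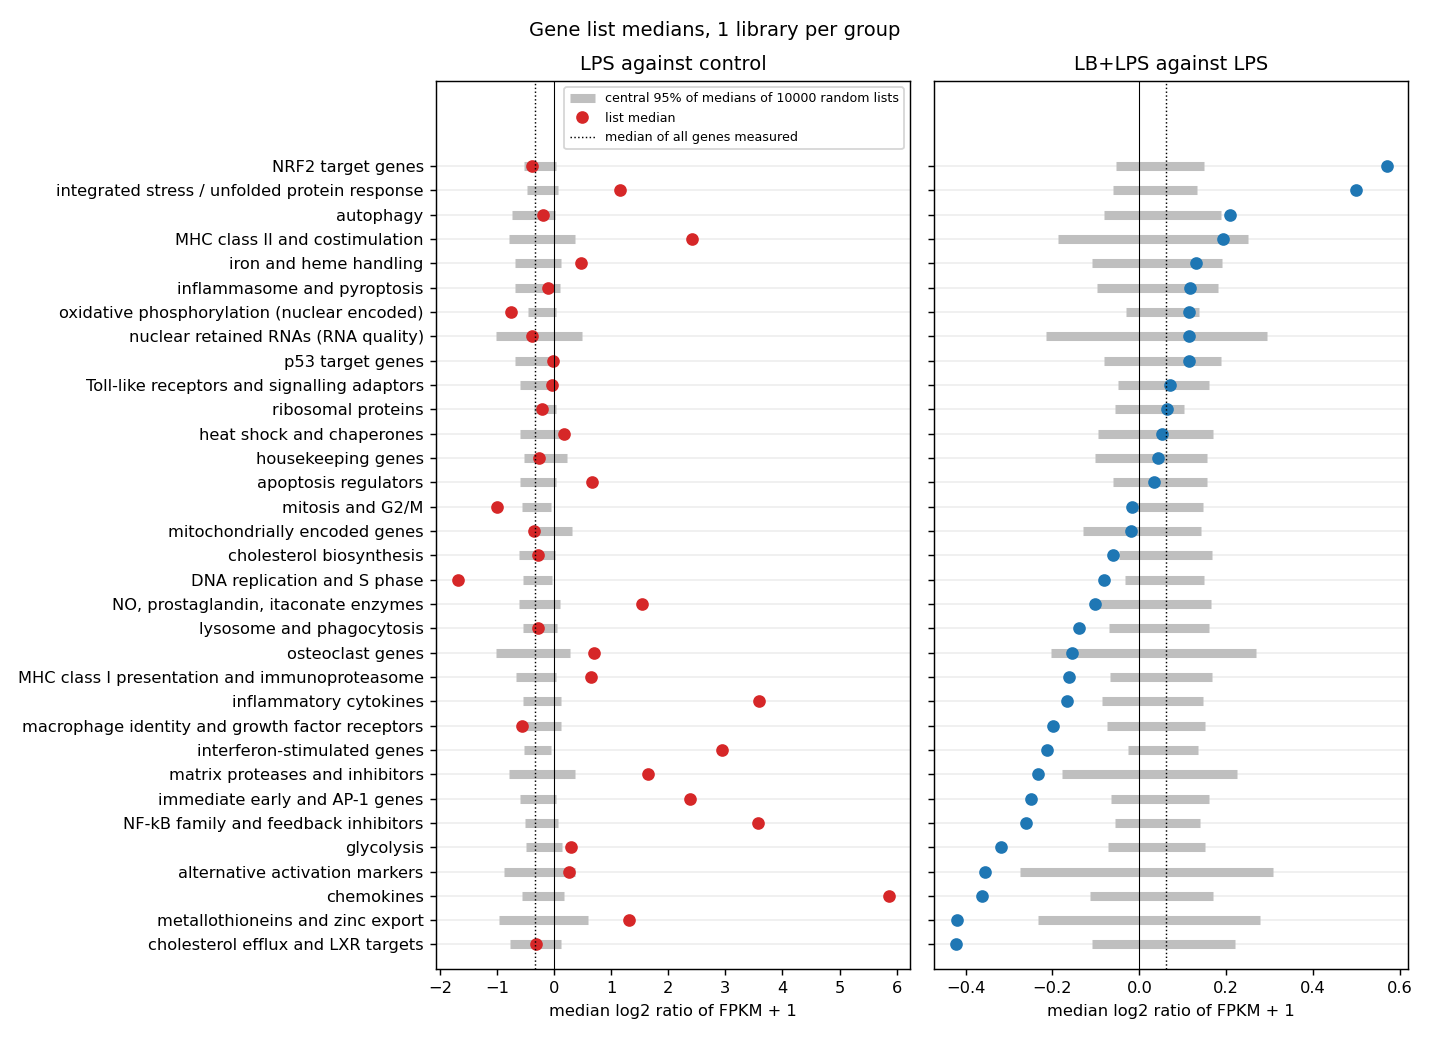
Median log2 ratio of FPKM + 1 of each gene list with at least 5 measured genes, for LPS against control (left) and LB+LPS against LPS (right), 1 library per group, as dots, with the central 95% of the medians of 10000 random lists matched on expression as grey bars and the median of all genes as dotted lines. On the right, NRF2 targets lie at 0.57 and cholesterol efflux genes at -0.42.

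The third comparison, LB+LPS against control, shows how far the response to LPS remained in the library that also received LB. Most of it was present. List medians for cytokines, chemokines and interferon-stimulated genes were 3.74, 6.00 and 2.87, beside 3.59, 5.86 and 2.95 without LB over slightly larger sets of measured genes. The NF-kB list stood at 2.65 beside 3.58, and S phase genes at -1.65 beside -1.69. Gene by gene, the NF-kB list had a median of -0.26 in LB+LPS against LPS, with 21 of 24 genes within 2-fold. The gap between its 2 medians against control is therefore not the change of a typical gene. Of 11724 genes 2694 differed at least 2-fold, 906 higher and 1788 lower (33.6% higher), with a median of all genes of -0.27. With size factors the split was 1191 higher and 1189 lower, or 50.0% higher. Among the 639 genes that differed at least 4-fold as deposited, 54.5% were higher.

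Among the 952 genes higher with LPS, LB+LPS kept a median of 91.0% of the log2 difference from control (bootstrap interval over genes 89.3 to 92.5), and 92 of them were at least 2-fold lower in LB+LPS than in LPS while 13 were at least 2-fold higher. Among the 1905 genes lower with LPS the median kept was 95.7% (94.7 to 96.7), with 21 at least 2-fold back towards control and 4 further away. With size factors the median kept was 100% over 1106 lower genes, so the 95.7% depends on the scaling. Because the LPS library enters both sides, genes picked for an extreme LPS value lie closer to control in another library by chance. In simulated libraries with no LB effect the share kept for the higher genes was 99.0%, 96.0% and 90.9% with coefficients of variation of 10%, 20% and 30%, and 0.45, 8.65 and 76.7 genes were at least 2-fold lower. At least 2-fold higher were 0.1, 2.5 and 21.9 of them, beside the 13 observed. For the lower genes the share kept was 98.7%, 96.1% and 92.3%, and 0.3, 9.85 and 107.5 genes were at least 2-fold back towards control, beside the 21 observed. Independent lists among the 10847 genes measured in both comparisons would share 12.1 genes where 92 were observed, 7.07 for the 21, 4.39 for the 13 and 19.5 for the 4, a count that leaves out the shared library. Of these 10847 genes, 952 were higher and 1534 lower with LPS, and 50 were higher and 138 lower in LB+LPS than in LPS. The 1534 and 50 are fewer than the 1905 and 63 of the full comparisons. Part of the excess may come from the shared LPS library, which cannot be split. The observed range of log2 ratios lay between those of the 10% and 20% settings, and that of the 30% setting was wider. At 10% and 20% the simulated counts were 0.45 and 8.65 of the higher genes, beside the 92 observed. Whether genes raised by LPS vary more between cultures than other genes was not measured.

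The largest genes against control were again Cxcl2 (2207 against 0.188 FPKM), Csf3 (1511 against 0.0414), Acod1 (2522 against 0.870) and Ptgs2 (2053 against 0.682). Ccl4 (2814 against 8.60 FPKM) was also among the 10 highest. Stress genes stood further from control than in the LPS library, with a list median of 1.86 for the integrated stress and unfolded protein responses (15 of 26 at least 2-fold higher), Sqstm1 12.4-fold higher and Hmox1 6.80-fold higher. NRF2 targets had 9 of 25 at least 2-fold higher and 4 lower (median -0.19, and 0.08 with size factors). The p53 target list had a median of 0.56 (percentile 100), with 10 of 18 genes above 0, over a larger measured set than the 16 genes of LPS against control. Cholesterol efflux and LXR targets had a median of -0.67 (percentile 3.30), with Abcg1, a sterol exporter gene, 102-fold lower (84.7 to 124) and Scd2 28.5-fold lower (27.7 to 29.4). Part of this was present with LPS alone, where Abcg1 was 14.8-fold (13.6 to 16.1) and Scd2 5.12-fold lower than control (5.04 to 5.20). Abcg1 was low in LB+LPS, at 0.172 FPKM and 112 counts. Macrophage identity genes had 10 of 20 at least 2-fold lower and 3 higher (median -0.94, percentile 0). Further genes among the 10 lowest were Ranbp3l (0.0566 against 69.6 FPKM), Kbtbd11 (0.490 against 46.3), Trem2 (1.20 against 48.8), Tk1 (1.72 against 44.1), Chst1 (0.215 against 17.9), Ndrg2 (4.70 against 75.5) and Gpr183, an oxysterol receptor gene (1.56 against 31.9).

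**Figure D3:**
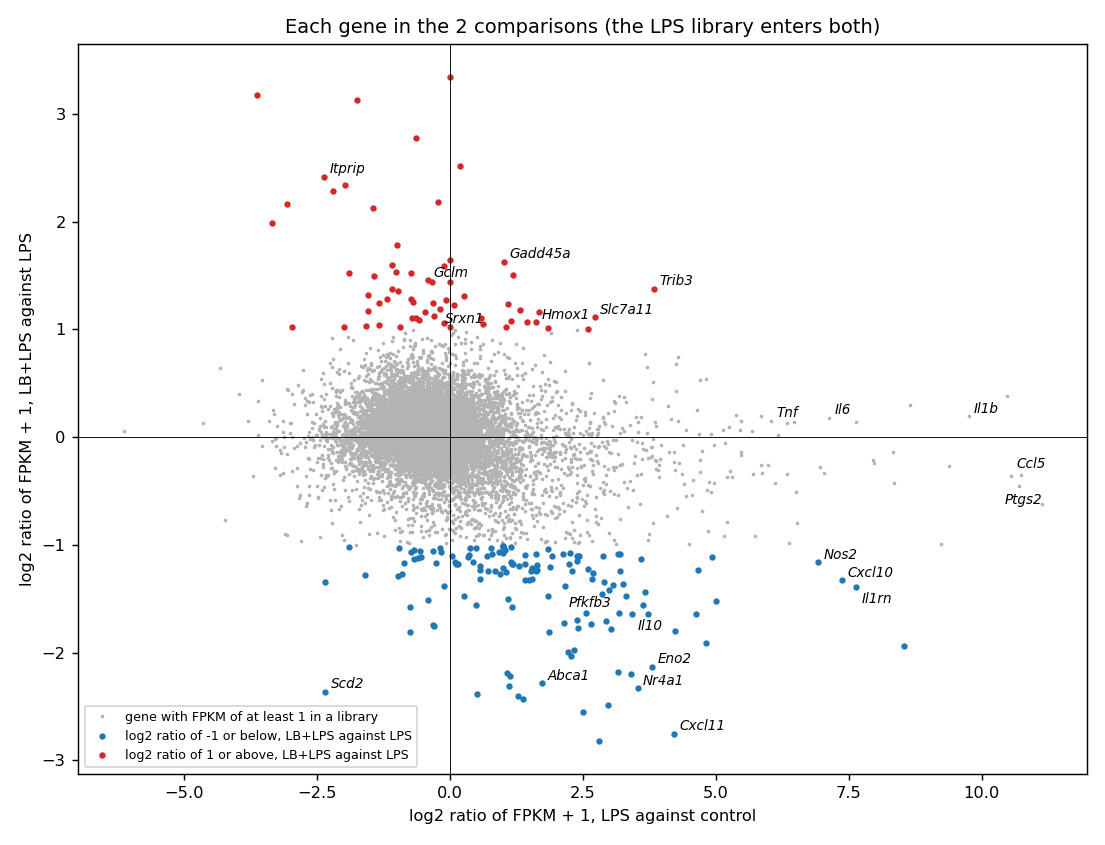
Log2 ratio of FPKM + 1 of each gene for LPS against control (horizontal axis) and LB+LPS against LPS (vertical axis), for genes with an FPKM of at least 1 in a library, with blue at -1 or below and red at 1 or above on the vertical axis, and the LPS library in both axes. Cxcl11 lies at -2.75 and Gclm at 1.46 on the vertical axis, and Tnf at 0.15.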

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

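The restriction to genes with a protein-coding transcript was chosen only after the results were seen. Counts of genes at least 2-fold different, for LPS against control, LB+LPS against LPS and LB+LPS against control (2857, 201 and 2694), were 1223, 59 and 1192 with a pseudocount of 5, 4668, 695 and 4212 after rescaling to TPM, 5601, 771 and 5171 at 1.5-fold, and 671, 28 and 639 at 4-fold. For LB+LPS against LPS the count was also 484 with a pseudocount of 0.1, 123 with a filter at an FPKM of 5, and 129 with protein-coding genes alone. Looser or stricter sizes, filters and pseudocounts move such counts by construction, and TPM raises all values so that a pseudocount of 1 acts as a smaller one. The share of the LPS response kept by the higher genes (91.0%) was 89.1% with size factors and 93.1% with the filter at 5. That of the lower genes (95.7%) was 92.7% with a pseudocount of 0.1, 99.4% with 5, 100% with size factors and 91.0% with TPM, and the cause was not tested. The inducible enzyme list in LB+LPS against control, with a median of 0.88, reversed to -0.18 with the filter at 5, which leaves fewer genes in the list. No other list median outside the central 95% of random lists changed sign. Of all other list medians under the alternatives, 545 stayed within the bootstrap interval of the reported value and 37 did not. No named gene with an absolute log2 ratio of at least 1 changed sign under another pseudocount or scaling, while 1281 such values for named genes lay beyond the counting interval and 551 within it. The unchanged sign follows by construction and is no independent support. A pseudocount added to both values keeps the sign. The scalings moved the median of all genes in LPS against control only from -0.34 to -0.04 or -0.45. With 1 library per group, depth limits only genes near the floor, and differences between cultures were not measured. No paired analysis was possible because each group has 1 column with no replicate number, and for that reason leaving out columns in turn and a replicate block, both foreseen for several columns per group, were not run.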

Other observations

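The table's own KEGG pathway annotation, with at least 15 measured genes per pathway, was scanned as a description chosen after the fixed lists had been seen. In LB+LPS against LPS, 19 of 277 pathways lay above the central 95% of random lists and 91 below it, and pathways share genes. The highest median was that of the proteasome, the main protease of damaged and ubiquitin-marked proteins (0.32, percentile 100, 36 of 45 genes above 0). Protein export (0.28, 29 of 31), protein processing in the endoplasmic reticulum (0.21, 123 of 146) and aminoacyl-tRNA biosynthesis (0.20, 35 of 43) followed the same direction, and their medians with size factors were 0.21, 0.14 and 0.12, with 0.24 for the proteasome. Cytokine-cytokine receptor interaction (-0.20, 62 of 94 below 0) and cell adhesion molecules (-0.16, 35 of 46 below 0) were lower.

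In LPS against control the same scan placed DNA replication (-1.44, 35 of 35 below 0) lowest of 281 pathways. Repair pathways were low as well, with mismatch repair at -1.26 (22 of 22 below 0), homologous recombination at -0.88 (39 of 39) and the Fanconi anemia pathway at -0.87 (47 of 48). Arachidonic acid metabolism stood at -1.31 (percentile 0, 15 of 19 below 0), biosynthesis of unsaturated fatty acids at -1.29 (percentile 0, 18 of 22) and fatty acid degradation at -0.87 (percentile 0.03, 28 of 34), while cholesterol metabolism (-0.31, percentile 52.9) and sphingolipid metabolism (-0.27, percentile 63.1) lay within the range of random lists. Complement and coagulation cascades stood at 1.22 (13 of 20 above 0).

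Of the tests below, those of library scaling, of transcript length and expression level and of single cultures were chosen after the pattern was seen, and those on further target genes were written before the values of these genes were looked at. For each of the 3 patterns, 1 library per group means that a difference between single cultures or libraries cannot be told apart from the treatment, and GC content was not tested. In LB+LPS against LPS, 19 of 33 fixed lists lay outside the central 95% of random lists. An extreme percentile alone therefore does not set a list of related genes apart.

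The first pattern is the higher level of NRF2 targets and stress genes in LB+LPS. A wrong library scale would move all genes alike, so it cannot make the gap of these 51 genes to the median of all genes. That gap stayed at least 0.434 under 3 scalings, which follows largely by construction and is no independent support. Transcript length and expression level as the whole cause are argued against by a percentile of 100 among lists matched on both. Higher ATF4 activity is a candidate explanation, as 27 further ATF4 targets, many of them tRNA synthetases, had a median of 0.38 at percentile 100, with 26 above 0. For higher NRF2 activity the evidence was thin, since 11 further targets had a median of 0.23 at percentile 97.7, with Ephx1 at -1.55 and Slc6a9 shared with the ATF4 list.

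The second pattern is the lower level of glycolysis genes in LB+LPS. The gap to the median of all genes was -0.379 or lower, which a library scale cannot make, again by construction rather than by test. Transcript length and expression level are argued against by a percentile of 0 among lists matched on both. A hypothesis is lower activity of the hypoxia response, which shares glycolytic targets. Its 24 further genes had a median of -0.38 at percentile 0, with 22 below 0, among them Ndrg1 at -1.33, Ero1a at -1.34 and Mxi1 at -1.12. Oxygen and HIF protein were not measured, so the hypothesis may stand for another shared regulator.

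The third pattern is the lower level of cholesterol efflux and LXR targets, led by Abca1. The smallest gap to the median of all genes was -0.483, which a library scale cannot make, by construction as above. Transcript length and expression level were argued against by a percentile of 0 among lists matched on both. Lower LXR activity stays open, since 11 further targets had a median of -0.06 at percentile 6.52, with 8 below 0.

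Some genes were chosen after their values were seen. Itprip had 1364, 49 and 1822 counts in control, LPS and LB+LPS. Guca1a had 0, 368 and 0 counts, and Gm50461, which overlaps it on the same strand, had 629, 0 and 261. Gapdh was listed at 16.6, 20.5 and 19.7 FPKM. The ribosomal RNA gene Rn18s-rs5 had 52961, 117129 and 29471 counts.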
